A study of Mus musculus with 8 samples.

How the data were processed

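RNA was measured in 8 libraries of sorted cells from the vagal ganglia of C57BL/6 mice. Per the labels' protocols, ganglia of 5 mice were pooled and dissociated for each library, and neurons were sorted by flow cytometry for the presence or absence of Fast Blue. Fast Blue is a fluorescent dye that travels back along axons from the tissue where it was placed, and the series describes airway-innervating neurons. Mice had received lipopolysaccharide (LPS, a bacterial cell wall component) or vehicle. The 4 groups of 2 libraries are vehicle negative, LPS negative, vehicle positive and LPS positive, taken from the titles and the characteristics. The labels describe every library as a pool of mice, and the 2 libraries of a group were taken as separate pools. The spread between the libraries of a group therefore includes differences between pools. A positive and a negative library of one treatment may share a pool.

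Per the submitters' processing notes, TopHat, Cufflinks and Cuffdiff were run against the mouse build mm9; their versions are not given in the sources used here. The authors deposited one Cuffdiff table per sort, with a line per gene, condition and replicate. Per the file headers, each line holds the raw fragments of a gene, which are estimated counts, and an FPKM value (fragments scaled by transcript length and library total). Cuffdiff divides fragments that fit several genes among them, so the deposited expected counts need not be whole: 98.1% of the values were whole, and 99.0% lay within 0.01 of a whole number. They were rounded to whole numbers. FPKM values were scaled by the authors within each table, so the reported comparisons were made on the counts. FPKM was used to rank and filter genes, and in an alternative test with limma, whose comparison across sorts rests on separately scaled values. The replicate numbers 0 and 1 of the tables were taken as groups 1 and 2 of the titles; no source states this, and the replicate numbers affect no comparison except the paired fits. The genome reference at hand was another build (GRCm38), so genes are named by the symbols in the tables and no coordinates are given.

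The tables list 23935 genes each. Of the genes listed in either table, 8 were left out: 3 whose text was damaged or missing in a table, and Malat1, Rn45s, Cmss1, Filip1l and Zc3h7a, which Cuffdiff had skipped in at least one library for an excess of fragments. This left 23928 genes that both tables hold, with 0 mitochondrial transcripts among them. Library totals ran from 10441754 to 17489169 fragments, and between 13277 and 14897 genes had at least 10 fragments in a library. Map1b was the gene with the most fragments in all 8 libraries, at 0.97% to 2.23% of the total.

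Genes with low counts were removed with filterByExpr of edgeR 4.0.16 (minimum count 10), libraries were scaled by TMM, and each comparison was tested with edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05 (R 4.3.3). LPS against vehicle was fitted in each sort on its own 4 libraries. The difference of the LPS effect between sorts was the interaction term over all 8 libraries, and positive against negative cells were compared in the vehicle libraries. For the interaction, the design written beforehand named limma; because the tables turned out to hold counts, edgeR was used. Standard errors are the log2 fold change divided by the square root of the F statistic. Levels are CPM, the fragments of a gene relative to the library total after TMM scaling over the 8 libraries, as mean ± SD of 2 libraries. With 2 libraries per group, the residual degrees of freedom are 2 for a comparison within a sort and 4 for the interaction, and the spread is shared between genes.

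Before the data were examined, 23 gene lists were written from general knowledge, after the series title, which names nerve injury, had been read. They cover nerve injury, inflammation, neuronal classes and the other cell types that the sort could hold. Each list with at least 3 tested genes was compared with the other genes by camera (limma 3.58.1, preset correlation 0.01), again by camera with a correlation estimated from the data, and tested by fry. Two-sided p-values were adjusted over the lists of a comparison. Members were also counted when adjusted over the list alone. The list calls are those of the preset correlation. No list in any of the 4 comparisons passed with an estimated correlation, where the smallest adjusted p was 0.366 for LPS in the positive sort, 0.649 in the negative sort, 0.215 for the difference and 0.15 for positive against negative.

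Genes were named by a rule fixed before the data were examined. It took the 12 largest rises and the 12 largest falls in FPKM (pseudocount 1) among genes past the threshold with an FPKM of at least 1, and Atf3 in every case. It took up to 4 members of each list described, those past the threshold first and then those with the largest mean FPKM. For positive against negative cells it took the 8 largest in each direction with an FPKM of at least 5, and for the difference between sorts the 6 largest in each direction past the threshold. Some genes that the rule takes are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

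Within each group, the libraries differed by more than sampling noise. A chi-square statistic over genes with at least 20 fragments was between 28.7 and 35.8 times its degrees of freedom, so the 2 libraries of a group were not copies of each other. LPS and vehicle pools are different mice, so their numbers do not pair them by mice. A positive and a negative library of one treatment and number were taken to come from one pool, from the sorting protocol; no source states it library by library, and a fit with the pool as a block was added for the comparisons between sorts. The pairing was checked by correlating, over 11170 genes, the difference between replicates 1 and 2 of a group with that of another group. The correlation was 0.20 between the vehicle sorts and 0.12 between the LPS sorts. It was larger, 0.50, between vehicle and LPS in the negative sort, which do not share mice, and 0.15 between vehicle and LPS in the positive sort. The check does not single out the sorts of one treatment as the pairs, and libraries with the same number share a pattern across treatments in the negative sort whose origin is not given in the sources used here.

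The scripts were tested on simulated counts made from the real means, library sizes and dispersions, with 200 changed genes. For LPS in the positive sort, 59.8% of 97 genes changed by 4-fold and 27.6% of 98 changed by 2-fold were recovered over 13500 genes. The shares were 86.7% and 25.8% for the negative sort over 14686 genes, 76.3% and 19.4% for positive against negative over 14281 genes, and 43.8% and 2.0% for the interaction over 14840 genes. False calls were 6 of 91, 9 of 119, 11 of 104 and 3 of 47. A planted list of 30 genes raised by 1.5-fold was found in each of the 4 comparisons, with 1 other list called in positive against negative cells and 0 in the others. The simulated genes were drawn independently of each other, so this does not test the preset correlation. In the real data the correlation estimated for the nerve-injury list in positive cells was 0.363.

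Alternatives chosen before the data were examined were an FPKM filter, a threshold of 0.01, a second pseudocount of 0.1, a minimum fold change, centring of the log2 ratios, a second adjustment over genes with an FPKM of at least 1 and, for LPS against vehicle, the replicate block, leaving out each library and DESeq2 1.42.0. RLE size factors, no filter on low counts, limma on log2(FPKM + 1), one fit over 8 libraries, the estimated correlation for the lists and, for the comparisons between sorts and the lists, the block and leaving out each library were added, with DESeq2 for the comparisons between sorts, after seeing the data.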

Results

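Gene expression was measured by RNA sequencing in sorted cells of mouse vagal ganglia, which hold the sensory neurons of the vagus nerve. The series examines airway-innervating neurons with and without lung inflammation. Neurons traced from the airways with Fast Blue (positive) and untraced cells (negative) came from mice given LPS or vehicle, with 2 libraries per group and 5 pooled mice per library. The negative libraries held 15137467 and 10441754 fragments after vehicle and 16560774 and 17489169 after LPS. The positive libraries held 15117142 and 16539216 fragments after vehicle and 16158525 and 15440982 after LPS. Levels are in CPM, fragments relative to the scaled library total, as mean ± SD with n = 2. The first principal component of the log2 levels took 59.8% of the variance and separated positive from negative libraries. On the second (13.8%), LPS positive replicate 1 stood apart at 35.6, against -3.5 for LPS positive replicate 2 and -27.0 and -16.9 for the vehicle positive libraries.

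The first comparison asks which genes differ between LPS and vehicle in the airway-traced neurons. After LPS, 16 genes rose and 1 fell, and 9 of the risen genes belong to the fixed list of genes induced by nerve injury. Sprr1a, a cornified envelope protein that sensory neurons make after axon damage, rose from 3.64 ± 1.2 to 49.3 ± 9.4 CPM (SD, n = 2), a log2 fold change of 3.75 ± 0.37 (SE). Gpr151, an orphan receptor, rose from 2.82 ± 1.4 to 49.9 ± 9.5 CPM, by 4.14 ± 0.41 on the log2 scale. Cdkn1a, a cell cycle inhibitor that responds to stress, rose from 52.7 ± 5.9 to 275 ± 77. The neurotrophin-induced precursor Vgf rose from 40.6 ± 15 to 210 ± 110. Lypd1, a modulator of nicotinic receptors, was the gene that fell, from 478 ± 62 to 196 ± 32. Adjusted p was 0.00505 for Sprr1a, Gpr151 and Cdkn1a, 0.0468 for Vgf and 0.0377 for Lypd1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13809 genes. For all of these, both LPS libraries lay on the same side of both vehicle libraries.

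Among the nerve-injury genes, all 31 tested members had higher values after LPS, with a median log2 fold change of 1.33. Of these, 9 rose when adjusted over all genes, and 22 when adjusted over the list alone. Besides Sprr1a and Gpr151, Sox11, a transcription factor of growing neurons, rose by 2.16 ± 0.26, and Cckbr, a cholecystokinin receptor, by 3.17 ± 0.44. The calcium channel subunit Cacna2d1 rose from 184 ± 18 to 584 ± 200 CPM and the adhesion protein Flrt3 from 97.8 ± 19 to 249 ± 20. Sez6l, Adcyap1 and Sema6a, the last chosen after its values were seen, were the other 3 members that rose. Atf3, a transcription factor switched on by axon injury, stood at 124 ± 20 after vehicle and 190 ± 46 after LPS, a log2 fold change of 0.60 ± 0.22 that did not pass over all genes (adjusted p = 0.555, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). As a group the list stood above the other genes by camera (adjusted p = 1.8e-51), with adjusted p = 0.366 with an estimated correlation. The test by fry, which asks whether the list moved one way without comparing it with other genes, gave adjusted p = 0.262. The list median was 1.24 and 1.25 in LPS replicate 1 against each vehicle library, and 0.80 and 0.64 in LPS replicate 2, the first being the library that stood apart on the second principal component. In the same libraries the satellite glia and Schwann cell list had a median of -0.07 and the immediate-early list of -0.21, with 0 of 17 and 0 of 16 members past the threshold over all genes, and 0 and 1 (lower) when adjusted over the list alone.

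**Figure D1:**
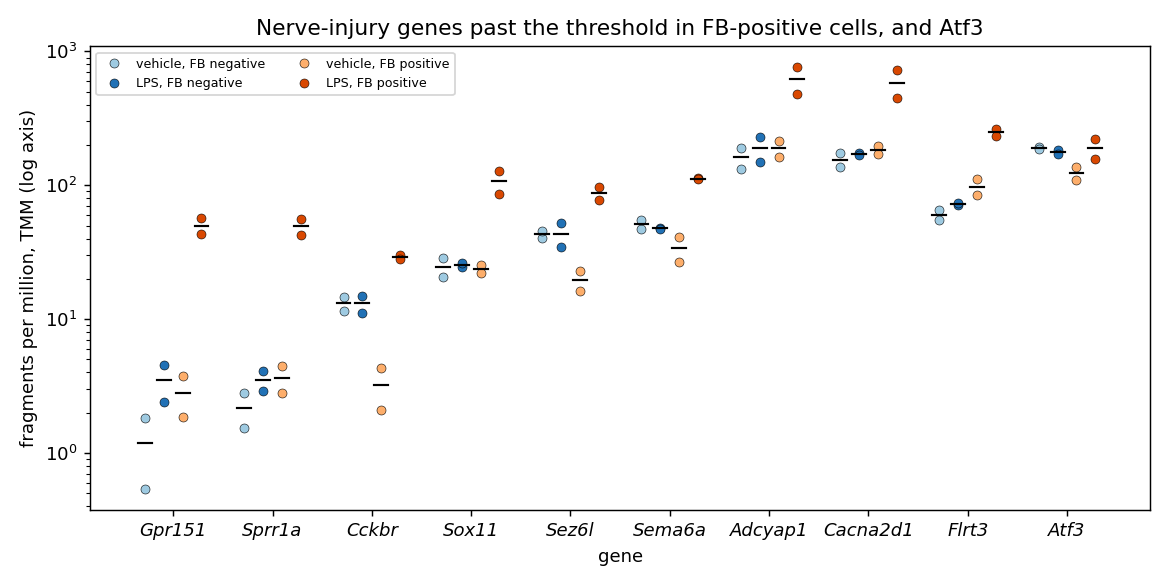
CPM after TMM scaling, on a log axis, of the 9 nerve-injury genes past the threshold in Fast Blue (FB) positive cells and of Atf3. Each point is 1 library, colours are the 4 groups of 2 libraries and black bars are group means; for each of the 9 genes both LPS positive libraries lie above the other 6.

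Neuropeptide genes had a median of 0.96 after LPS in the traced neurons, with 9 of 12 members higher. Of these, Adcyap1, Gal, Npy, Nts and Vip are also on the nerve-injury list and had a median of 1.71, while the 7 others had a median of 0.32, with 4 higher (unadjusted camera p = 0.0535, and p = 0.212 with an estimated correlation; this split was chosen after the values were seen). Adcyap1, the precursor of PACAP, rose from 188 ± 35 to 619 ± 200 CPM and was the 1 member past the threshold over all genes, against 6 when adjusted over the list alone. Calca, the CGRP precursor, stood at 128 ± 59 and 277 ± 140, Tac1, the substance P precursor, at 107 ± 2.2 and 149 ± 21, and Cartpt at 75.2 ± 23 and 134 ± 46. These 3 did not pass over all genes. The camera adjusted p for this list was 1.8e-07, and adjusted p = 0.366 with an estimated correlation.

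Of the interferon-stimulated genes, 22 of 24 were higher (median 0.65), with 0 past the threshold over all genes and 4 when adjusted over the list alone. Ifitm3, an antiviral membrane protein, stood at 22.2 ± 5.1 after vehicle and 50.7 ± 11 after LPS. Oasl2 and Stat2 had log2 fold changes of 0.16 ± 0.22 and 0.31 ± 0.22. The NF-kB and acute inflammation list (median 0.50, 12 of 17 higher) and the STAT3 response list (median 0.30, 12 of 14 higher) share their 1 member past the threshold, Timp1, a metalloproteinase inhibitor, which rose from 0.389 ± 0.15 to 9.94 ± 1.4. When adjusted over the list alone, 3 and 1 members passed. The camera adjusted p was 1.8e-07 for the interferon list, 4.29e-04 for the NF-kB list and 0.0193 for the STAT3 list, and adjusted p = 0.522 with an estimated correlation for each of the 3. The macrophage markers detected in these libraries had a median of 0.73 with 0 of 7 past the threshold, and Cd74 stood at 1.38 ± 0.77 and 4.86 ± 4.8 CPM.

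The remaining risen genes named by the rule were Tifa, an adaptor of innate immune signalling (19.6 ± 0.66 to 95.4 ± 26 CPM), the sulfotransferase Chst2 (63.1 ± 21 to 231 ± 29), and Cyp26a1, which degrades retinoic acid (1.87 ± 0.72 to 26.6 ± 16). Rps27, chosen after its values were seen, passed the threshold (59.7 ± 8.9 to 165 ± 16) but shares reads with its near-identical copy Rps27rt and is uncertain. With the fragments of both genes summed, the log2 fold change was 1.06 ± 0.22 with adjusted p = 0.24 by edgeR's quasi-likelihood test. Of the 15 other lists with at least 3 tested genes, the fibroblast list (median -0.61, 5 of 6 lower) had a camera adjusted p of 0.0677 and a fry adjusted p of 0.00837. The other 14 did not pass by camera or fry. Their medians ran from -1.03 for mural cells to 0.73 for macrophages, and those of the pan-neuronal, nodose and jugular lists were 0.02, -0.29 and -0.33. The pan-neuronal and cell cycle lists had means of the opposite sign to their medians, and the mural list was placed upward by camera against a negative median.

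The counts of genes and lists for LPS in positive cells depended on the libraries kept, and a fit without 1 library leaves a lone library in a group. The 17 genes kept the sign of their log2 fold change over 13 alternatives, these fits among them. For all 17, both LPS libraries lay on the same side of both vehicle libraries. The sign was therefore close to fixed beforehand and says little about stability. Each of the 17 lost its call in 2 to 5 of the 13 alternatives. The log2 fold change of Sprr1a lay between 3.43 and 4.14, that of Adcyap1 between 1.325 and 2.015 and that of Timp1 between 3.18 and 5.08. Without vehicle replicate 2 the NF-kB and STAT3 lists did not pass (adjusted p = 0.104 for each), nor did the STAT3 list without LPS replicate 1 (0.0736), while without vehicle replicate 1 the medians of the NF-kB and interferon lists were 1.32 and 1.10. The nerve-injury median stayed between 0.82 and 1.43 when any 1 of the 4 libraries was left out.

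The second comparison applies the same contrast to the untraced cells. No gene passed the threshold there: edgeR called 0 of 14874 genes, with 394 at an unadjusted p below 0.05. DESeq2 called 7, and limma on log2(FPKM + 1) called 25, all of them small RNAs. Vehicle and LPS libraries of one number shared deviations in this sort (correlation 0.50), and the fit with the number as a block called more genes. These libraries come from different mice, and no source says what the number stands for. The smallest adjusted p, 0.0527 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, belonged to complement C3, chosen after its values were seen, at 3.25 ± 0.25 CPM after vehicle and 19.4 ± 2.1 after LPS (log2 fold change 2.57 ± 0.27). C3 passed in 7 of 13 alternatives, among them DESeq2, with adjusted p from 1.03e-08 to 1 over the 13. Other acute phase and interferon genes chosen after their values were seen were Lcn2 (0.654 ± 0.29 and 4.70 ± 2.1), Lrg1 (0.861 ± 0.70 and 7.27 ± 0.35) and Gbp2 (40.2 ± 7.7 and 108 ± 18), which did not pass by edgeR. With DESeq2, Gbp2 (adjusted p = 3.89e-04) and Lrg1 (adjusted p = 7.32e-04) passed, and with no filter on low counts Gbp2, Lrg1 and Lcn2 did. The DESeq2 calls also held 4 lower genes of the extracellular matrix, chosen after their values were seen: Col15a1 (log2 fold change -1.66), Col3a1 (-1.67), Fn1 (-1.26) and Postn (-1.51), which also passed as lower with no filter, as did Lum. Gbp2 was also higher after LPS in positive cells, at 10.3 ± 1.6 and 34.4 ± 0.25 CPM (log2 fold change 1.72 ± 0.32). It did not pass there (adjusted p = 0.12 by edgeR), but did in one fit over all 8 libraries (adjusted p = 0.0185). In those cells C3 was lower, at 3.44 ± 2.7 and 1.23 ± 0.21 CPM, and Lcn2 and Lrg1 were not tested. Atf3 stood at 189 ± 4.2 and 178 ± 8.2 CPM in the negative cells. The count of genes was 73 without vehicle replicate 1, 22 without vehicle replicate 2, 0 without LPS replicate 1 and 1 without LPS replicate 2.

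By camera, 11 lists passed in the negative cells. Interferon-stimulated genes were higher in 23 of 25 cases (median 0.52, 2 past the threshold when adjusted over the list alone and 0 over all genes), with Ifitm3 at a log2 fold change of 0.49 ± 0.30, Oasl2 at 0.35 ± 0.23 and Stat2 at 0.05 ± 0.22. The NF-kB and acute inflammation list had a median of 0.36 with 20 of 27 higher, 2 past the threshold when adjusted over the list alone and 0 over all genes. Cxcl10, a chemokine, stood at 74.0 ± 46 after vehicle and 120 ± 51 after LPS, while the chemokine Cxcl1 stood at 31.9 ± 16 and 20.2 ± 4.7. Fibroblast genes were lower in 7 of 9 cases (median -0.94, 0 past the threshold over all genes). Adjusted over the list alone, 6 fell and 1, Mgp, rose. Col3a1, a fibrillar collagen, stood at 192 ± 69 and 60.9 ± 28 CPM and Col1a2 at 181 ± 71 and 94.2 ± 5.9, while Dcn stood at 340 ± 170 and 268 ± 56. The camera adjusted p was 5.24e-16, 1.76e-08 and 5.43e-08 for these 3 lists, and adjusted p = 0.649 with an estimated correlation for each. By fry no list passed in the negative cells (smallest adjusted p = 0.752).

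For the other 8 lists, medians were 0.10 for nerve injury, 0.23 for neuropeptides, 0.10 for sensory channels and receptors and 0.22 for macrophages, and -0.23 for immediate-early, -0.22 for satellite glia and Schwann cells, -0.26 for mural cells and -0.44 for cell cycle genes. None of the 8 had a member past the threshold, over all genes or when adjusted over the list alone, and adjusted p was between 0.649 and 0.696 with an estimated correlation. Of the 11 lists, 1, interferon-stimulated genes, passed without each of the 4 libraries in turn, and its median was 0.26 without LPS replicate 1 and 0.80 without LPS replicate 2. The fibroblast list did not pass without vehicle replicate 1 (median -0.50, camera adjusted p = 0.0832). The medians of the macrophage (-0.16) and glial (0.02) lists changed sign without LPS replicate 1, and that of the NF-kB list (-0.08) without vehicle replicate 2. The count of lists was 7 without either vehicle replicate and 5 without LPS replicate 1.

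**Figure D2:**
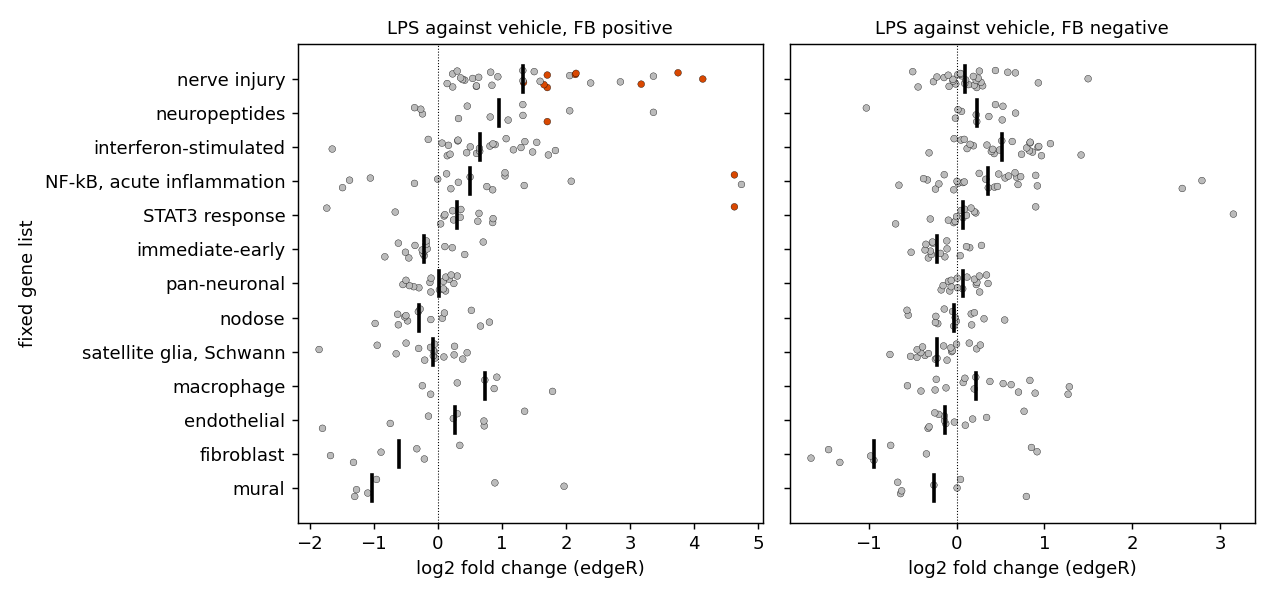
Log2 fold change of LPS against vehicle (horizontal axis) of each tested member of 13 fixed gene lists, in Fast Blue (FB) positive cells at left and negative cells at right. Orange points passed the threshold over all genes, grey points did not, and black bars are list medians; the nerve-injury median is 1.33 in positive cells and 0.10 in negative cells.

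The third comparison asks whether the LPS effect itself differs between traced and untraced cells. No gene passed the interaction test: edgeR called 0 of 15191 genes, with 704 at an unadjusted p below 0.05. DESeq2 called 17, and limma on log2(FPKM + 1) called 1, a small RNA. With the pool of mice as a block, Chst2 passed as the 1 gene (difference 2.33 on the log2 scale, adjusted p = 0.0095 by edgeR). The nerve-injury list was the 1 list past the threshold. Its 31 tested members all had a larger log2 fold change in positive than in negative cells, by a median of 1.08, with 0 past the threshold over all genes and 14 when adjusted over the list alone. Its camera adjusted p was 1.95e-30, and adjusted p = 0.215 with an estimated correlation. The fry adjusted p for the list was 0.248. With the block, the neuropeptide list also passed (median difference 0.55, camera adjusted p = 0.0362), with adjusted p = 0.639 with an estimated correlation. Genes with the smallest p, chosen after their values were seen, were Cdkn1a (difference 2.03 ± 0.32) and Chst2 (2.32 ± 0.36), each with adjusted p = 0.277 by edgeR's quasi-likelihood test. Sprr1a differed by 3.11 ± 0.56 (same adjusted p), being at 2.18 ± 0.90 and 3.51 ± 0.85 CPM in the negative cells. As 0 genes were called in the negative cells, the calls of the 2 sorts shared 0 of the 13624 genes tested in both, and an overlap test says nothing. The difference for Rps27, whose reads are split unevenly with Rps27rt, was -4.32 without vehicle negative replicate 1, against -0.07 with all 8 libraries. The count of lists was 7 without vehicle negative replicate 2, 4 without LPS negative replicate 1 and 5 without vehicle positive replicate 1.

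The fourth comparison describes how traced and untraced cells differed in vehicle mice. Of 14605 genes, 379 were higher and 1033 lower in positive cells past the threshold, and the largest falls were in genes of cells other than neurons. Past the threshold, 17 of 17 macrophage markers fell (median -4.20), as did 8 of 8 fibroblast genes (median -4.64), 11 of 12 endothelial genes (median -3.85) and 4 of 7 mural genes (median -2.16, and -6.23 without vehicle positive replicate 2). Cd74 stood at 59.4 ± 19 CPM in negative and 1.38 ± 0.77 in positive cells, Dcn at 340 ± 170 and 13.6 ± 2.1, and the endothelial cadherin Cdh5 at 36.2 ± 4.5 and 1.91 ± 0.82. Of the glial list, 10 of 19 members fell, among them the myelin gene Mbp (log2 fold change -1.97 ± 0.23), and 1, S100b, rose. Neutrophil markers had a median of -2.51 with 0 of 3 past the threshold over all genes and 3 when adjusted over the list alone.

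Pan-neuronal genes had a median of 0.57, with 6 of 17 higher past the threshold. Thy1 stood at 237 ± 8.5 and 850 ± 29 CPM, the neurofilament Nefh at 282 ± 75 and 863 ± 240 and Avil, an actin regulator of sensory neurons, at 161 ± 44 and 433 ± 15. Of the nodose list, 12 of 15 genes were lower (median -0.93), 7 of them past the threshold, among them Glp1r, the receptor for glucagon-like peptide 1 (50.2 ± 11 and 8.55 ± 1.9), and Cckar, a cholecystokinin receptor (370 ± 74 and 109 ± 38). Among sensory channels and receptors, 6 rose, including the mechanosensitive channel Piezo2 (138 ± 38 and 290 ± 48), and 2 fell, including Htr3b. Of the immediate-early genes, 16 of 16 were lower (median -1.22), 11 of them past the threshold, such as Fosb (578 ± 2.4 and 165 ± 4.0) and Egr1 (2430 ± 450 and 1030 ± 140). Inflammatory lists were lower too, with 9 of 24 NF-kB genes, 8 of 25 interferon-stimulated genes and 5 of 14 STAT3 response genes past the threshold (medians -1.87, -0.93 and -0.68). Examples are Cxcl1 (31.9 ± 16 and 3.78 ± 2.2), Gbp2 (40.2 ± 7.7 and 10.3 ± 1.6) and Fgl2 (32.4 ± 15 and 2.40 ± 0.22). These 3 lists did not pass by fry (adjusted p = 0.0892, 0.0886 and 0.0892). Macrophage, fibroblast and endothelial markers were also higher in the negative cells, so the inflammatory differences cannot be assigned to neurons.

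The largest rises were Pappa2, a protease of insulin-like growth factor binding proteins (17.6 ± 1.8 and 209 ± 17), Kcng1, a potassium channel subunit (1.08 ± 0.38 and 17.9 ± 8.0), the serotonin receptor Htr1d (3.99 ± 0.88 and 31.7 ± 17), Lgi3 (7.50 ± 0.13 and 51.8 ± 13) and Prkcb, a protein kinase C (62.6 ± 8.7 and 333 ± 49). Serpina3g, D930028M14Rik and Gm16551 completed the 8. The largest falls included Apod, a lipocalin (467 ± 230 and 14.1 ± 1.0), Rgs5 (37.5 ± 0.16 and 0.836 ± 0.49), Ccl11 (21.1 ± 7.7 and 0.319 ± 0.25), Col1a1 (127 ± 77 and 2.87 ± 0.89) and H2-Aa (29.4 ± 11 and 1.23 ± 0.55). Adjusted p lay between 9.57e-05 for Pappa2 and 0.00224 for Htr1d by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

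The camera test placed 11 lists below and 1 above the other genes, and adjusted p was between 0.15 and 0.341 with an estimated correlation. By fry the fibroblast list (adjusted p = 0.0538) and the 3 inflammatory lists did not pass. The other lists called by camera did (0.0481 to 0.0489 by fry). For nerve-injury genes the baseline median was -0.03, with 1 of 30 higher and 5 lower past the threshold. When the median ratio of genes with an FPKM of at least 5 in both sorts was set to 0, a shift of 0.18 on the log2 scale, 237 genes were higher and 1408 lower past the threshold, and Tubb3, a neuronal tubulin, and P2rx3, an ATP-gated channel, no longer passed. On that scale 4 sensory channels and receptors passed as higher and 3 as lower, and 0 nerve-injury genes as higher and 8 as lower. With the pool of mice as a block, 2360 genes passed (848 higher and 1512 lower), against 1412 without it, and the neutrophil list did not pass (camera adjusted p = 0.0631). Without vehicle negative replicate 2, 590 genes passed and the NF-kB median was -2.99. The interferon median was -0.58 without vehicle positive replicate 2, and the neutrophil list lost its call without that library (adjusted p = 0.122) or without vehicle negative replicate 1 (0.0539) or 2 (0.0992).

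**Figure D3:**
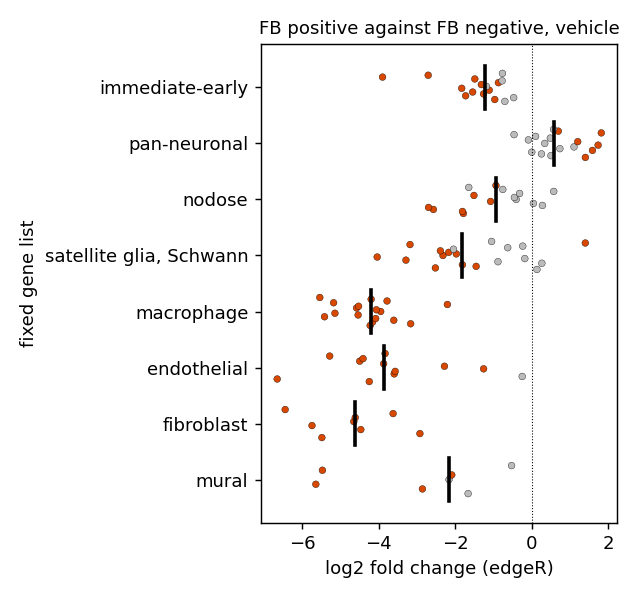
Log2 fold change of Fast Blue (FB) positive against negative cells in vehicle mice (horizontal axis) of each tested member of 8 fixed gene lists. Orange points passed the threshold over all genes, grey points did not, and black bars are list medians; medians run from -4.64 for fibroblast genes to 0.57 for pan-neuronal genes.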

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

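The tests of the glial and the immediate-early explanation were chosen after their values had been seen; the bound for single pairs of libraries was set before.

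The difference between sorts in the nerve-injury list was flagged because it passed by camera with the preset correlation. The median difference of the log2 fold changes, positive minus negative, was 1.08, and the median rise was 1.33 in positive cells. More glial RNA is argued against by the glial list: a larger share of satellite glia or Schwann cells would lift it by about as much, and its median was -0.071 in the positive sort and 0.21 (SD 0.721 over 19 genes) for the difference between sorts. Stronger dissociation stress would lift the immediate-early list, which was not higher: its median was -0.213, with 12 of 16 members lower after LPS in the positive sort. The same number were lower in the negative sort (median -0.23), and the median difference was 0 (SD 0.419). The bound of 12 lower members was set after these values were seen, so this list does not decide the explanation. Nor did 1 library alone carry the rise, as the lowest median over the 4 pairs of an LPS and a vehicle library was 0.636. LPS itself remains an open explanation, as do differences between pools in tracing or injection injury and in the mix of traced neurons, which were not tested with 2 pools per group, and the difference did not pass with an estimated correlation (adjusted p = 0.215).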

How the results depend on the processing

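Settings that had not been planned before the data were examined are named in the account of the processing. A fit without 1 library assumes that the lone library of a group varies like the other group. For LPS in positive cells, the count of 17 was 3 at a threshold of 0.01, 102 with DESeq2, 69 with no filter on low counts and 10 with limma on log2(FPKM + 1), of which 9 are small RNAs, and 0 to 262 without 1 library. In negative cells the count of 0 was 1 when adjusted again over genes with an FPKM of at least 1, 7 with DESeq2, 11 with no filter, 25 with limma on FPKM (25 of them small RNAs) and 0 to 73 without 1 library. LPS and vehicle pools are different mice, and no source says what a shared number stands for. Replicate deviations correlated at 0.50 between vehicle and LPS in negative cells, so an effect carried by the number cannot be excluded. With the replicate block the counts were 340 and 120, and those of lists 5 and 8. For positive against negative the count of 1412 was 494 at a threshold of 0.01, 2309 with no filter, 2360 with the replicate block of pools and 590 to 1862 without 1 library. For the difference between sorts the count of 0 was 17 with DESeq2, 75 with no filter, 1 with limma, 1 with the replicate block and 0 to 1 without 1 library. The lists past the threshold, 5 in positive cells, 11 in negative cells, 12 between sorts and 1 for the difference, were 0 in each case with an estimated correlation. Without 1 library they were 3 to 8, 5 to 9, 11 to 12 and 1 to 7, and for the difference 4 with members of an FPKM of at least 1 and 2 with the replicate block. In negative cells the median changed sign for the NF-kB list without vehicle replicate 2 (-0.081 to 0.809 without 1 library) and, without LPS replicate 1, for the glial (-0.511 to 0.015) and the macrophage list (-0.16 to 0.708). The other 60 recomputed counts lay within 1.5 times the reported one, but not all of them could move. The overlap of calls between sorts was 0 in any case, as 0 genes were called in negative cells. The minimum fold change left the same 17 genes in positive cells. Of 20 gene results for LPS that were followed through the alternatives, 0 changed sign. For the 17 called genes this was close to fixed beforehand, as both LPS libraries lay on the same side of both vehicle libraries. Each of the 17 genes past the threshold in positive cells lost its call in 2 to 5 of 13 alternatives, with adjusted p up to 0.95: 17 lost it without vehicle replicate 1, 17 without vehicle replicate 2 and 16 with limma on FPKM. The cause of these changes was not tested. In simulated counts at these library sizes, 2-fold changes were recovered less often than 4-fold changes; depth was not varied.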

Other observations

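The tests in this part were chosen after the values had been seen, except the bound for single pairs of libraries.

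The genes of this paragraph other than Trpa1 were chosen after their values were seen. Y-linked transcripts were at most 1 fragment per library for Ddx3y and 0 for Eif2s3y, Kdm5d and Uty in all 8 libraries, while Xist reached at least 348 CPM in each, the pattern of female mice. Xist varied within the negative sort, from 374 and 826 CPM after LPS to 918 and 1489 after vehicle, and stayed between 348 and 450 in the positive sort. Trpa1, the irritant channel, stood at 311 ± 28 CPM after vehicle and 602 ± 220 after LPS in positive cells and at 206 ± 8.9 and 221 ± 32 in negative cells, and did not pass in either (adjusted p = 0.362 in positive cells by edgeR).

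The fibroblast list had a median of -0.94 after LPS in the negative cells, with 0 of 9 members past the threshold over all genes by edgeR, 1 with DESeq2 (Col3a1), 2 with no filter on low counts (Col3a1 and Lum) and 5 without vehicle replicate 2 (Col1a1, Col1a2, Col3a1, Col6a1 and Lum). A smaller share of all cells that are not neurons is not settled by the macrophage list. Its median was 0.219, or -0.16 without LPS replicate 1, where the fibroblast median was -1.01. The glial (-0.222), mural (-0.258) and endothelial (-0.13) lists had negative medians, each a smaller fall than that of the fibroblast list. A loss of all such cells as large as the fibroblast fall is therefore argued against, and a smaller loss is not. One library may account for much of the fall, since the highest of the 4 pair medians was -0.086, in a pair with vehicle replicate 2, and without vehicle replicate 1 the list median was -0.50 with a camera adjusted p of 0.0832. A smaller share of fibroblasts cannot be told apart from lower expression, because Dcn, the most abundant of these genes, had a log2 fold change of -0.343 ± 0.32, within 2 standard errors of the list median. Mgp, at 0.85 ± 0.30, speaks against an equal loss of all 9 genes, but it is 1 gene and other cell types also make it.

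Rps27 shares reads with Rps27rt, and the fragments were split unevenly: in vehicle negative replicate 2, Rps27 stood at 1.90 and Rps27rt at 48.0 CPM, against 70.2 and 2.26 in replicate 1. With both genes summed, the difference in positive cells was 1.065 ± 0.225 on the log2 scale, against 1.46 ± 0.20 for Rps27 alone. The sum did not pass the threshold there (adjusted p = 0.24 by edgeR), because its fold change is smaller at a similar standard error. In negative cells the sum differed by 0.804 ± 0.219 and did not pass either. An uneven split cannot change the sum. In positive cells the sum stood at 182 and 154 CPM after LPS and at 93.1 and 66.1 after vehicle. These values argue against the split alone as the explanation there, while the size of the difference remains uncertain.

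A hypothesis is that the genes that rose in traced neurons also rise, by less, in the untraced cells. Of the 15 risen genes tested there, 12 had a positive log2 fold change, with a median of 0.23 against 2.22 in the traced neurons. Camera gave p = 0.00135 with the preset correlation but p = 0.0758 with an estimated one, and fry p = 0.0697, so the hypothesis cannot be told apart from chance with these libraries, and the highest value, 1.56, belongs to Rps27, which is uncertain.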
